A study of Danio rerio with 140 samples.

How the data were processed

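RNA-seq data of 17 whole primary melanomas, 18 sorted pools, 18 plate pools and 87 single cells of zebrafish were used. Whole tumours were dissected and dissociated, and libraries were made from polyadenylated RNA with a TruSeq kit and sequenced as paired ends. Pools and single cells were living cells positive for mitfa:GFP, isolated by flow sorting, and their libraries were made with SMARTseq2 and Nextera XT. Primary sorted pools held 50 cells, and regressed pools 37, 68, 69 and 40 held 50, 50, 10 and 11 cells. Control and primary plate pools held 50 cells, and the regressed plate pools 10 and 5 cells.

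For the 35 libraries of whole tumours and sorted pools the deposited values were whole-number read counts per gene, made by the authors with STAR 2.5.1b and HTSeq 0.6.1 on genome build GRCz11. For the 105 libraries of plate pools and single cells the deposited values were Salmon's estimated counts per transcript, with no further scaling. The same deposited files give TPM, transcripts scaled by the authors' Salmon run for length and depth, which were used only in an alternative. Per the submitters' processing notes reads were checked with FastQC 0.11.3 or 0.11.4 and trimmed with cutadapt; the versions of cutadapt and Salmon, the annotation release, the strand setting and any filter were not given in the sources used here. The count tables held 31465 Ensembl genes, GFP and the human BRAF transgene (hsBRAF), plus HTSeq summary entries, which took 20.6 to 85.5% of the reads of a library and were left out of all totals. Reads outside any feature amounted to 8.71 to 14.5% of the assigned and unassigned reads together in whole tumours, 10.8 to 77.6% in primary and 20.8 to 51.2% in regressed sorted pools. The Salmon tables held 53224 transcripts and 92 spike-in entries, and the latter were left out.

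Symbols were taken from a reference table that named 28965 of the genes in the style of human symbols, so genes that share a symbol are given with their identifier. Transcripts were not summed to genes, because no table that pairs the transcript identifiers with genes was used here. The summing to genes that was set down before the data were examined was therefore replaced by tests per transcript, and neither symbols nor gene lists were used for plate pools and single cells.

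Genes were tested with edgeR 4.0.16 in R 4.3.3 on TMM-scaled counts. The filter was filterByExpr, dispersions came from estimateDisp, the fit was glmQLFit with robust estimation, and the test was the quasi-likelihood F test. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons by genotype and by direction of growth used 1 fit of the 17 tumours in 3 groups, and that by pigment a fit in 4 groups. Sorted pools were fitted in 2 groups, and plate pools in 3 groups with the sequencing run as a term. CPM in the text are TMM-scaled unless stated to be over all reads, as are those in both plots, the sums of lists and the values of hsBRAF and GFP in the closing part. Errors of CPM are SD and errors of log2 fold changes SE. Groups were taken from the labels. The p-values measure only the spread between these samples, and the labels do not say which pools came from the same fish.

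The 23 gene lists (374 distinct symbols, of which 29 had no match) were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using an estimated correlation, and with fry, and adjusted over the lists of a comparison. They covered melanin and melanosome, neural crest, glia, neural crest stem-like state, iridophore, xanthophore, cell cycle, ERK output, p53 targets, matrix and mesenchyme, macrophage and granulocyte, T and NK cells, keratinocyte, skeletal muscle, erythrocyte, endothelium, immediate early, interferon response, sterol synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes. Comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes were named if they were among the 5 largest rises or falls past the threshold with a mean log2 CPM of at least 3 and a symbol, among the 3 members with the smallest p of a list that passed camera, or MITF, SOX10, BRAF, mki67 or DCT. Some genes that this rule names are not reported here. The transgenes were added after their values were seen. Transcripts of the plate pools were named by identifier with a narrower rule. It took fewer of the largest rises and falls at the same threshold and mean, without lists or fixed genes. In single cells, transcripts were ranked by the difference in the share of cells with at least 5 reads among those with a mean of at least 20 CPM in 1 group and at least 4 times the mean of the other.

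Alternatives comprised DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, other count filters, fits of only the groups compared, leaving out single libraries, and subsets by cells, depth or run. A library was called MALAT1-rich with over 10% of its assigned reads in MALAT1, and alternatives with these libraries, with pigmented tumours alone, without primary plate pools 5 and 6, and without regressed cell 29 were chosen after seeing the data. Shares of cells have exact Clopper-Pearson 95% intervals. The floor for a group at 0 was 3 counts over the group. Each bound is over all reads, and is the lower of those from the pooled reads and from the mean CPM of the other group, while list medians at the floor use pooled reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

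The fits were tested on simulated data with the group sizes and depths of each comparison. At 4-fold changes the simulated genotype, growth and pigment comparisons recovered 37.5, 52.5 and 33.3% of the changed genes, and the sorted pools 0%. At 32-fold changes the sorted pools recovered 24.3% and the plate pools 57.6, 25.0 and 25.7% in the order given in the results. False calls made up 4.92, 3.70, 2.83 and 6.06% of calls in the first 4 comparisons and 13.8, 0 and 17.2% in the plate pools. Where no gene was changed, 0 genes were called except for 1 in the comparison of primary with control plate pools. The simulation drew each gene independently and held no structure such as the MALAT1-rich libraries, so these rates need not hold in the real data.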

Results

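RNA was sequenced from 140 zebrafish samples that comprised 17 whole primary melanomas, 18 pools of sorted cells, 18 plate pools and 87 single cells. All tumours arose in fish with the mitfavc7 allele, a temperature-sensitive form of the melanocyte regulator mitfa, and a p53 mutation. Double tumours carried these alleles alone, and triple tumours also carried a mutant human BRAF transgene under the mitfa promoter. The whole tumours comprised 5 double superficial, 4 triple superficial, 2 triple nodular pigmented and 6 triple nodular amelanotic melanomas. The pools and single cells were living cells with mitfa:GFP fluorescence, sorted from triple primary melanomas and from sites of regressed triple melanoma. Part of the plate pools came from control fish. Their labels give mitfavc7 alone, except for 1 control pool whose label gives no genotype and which was grouped by its title. The sorted pools comprised 14 primary and 4 regressed pools, the plate pools 10 control, 6 primary and 2 regressed pools, and the single cells 56 primary and 31 regressed cells. Between 34373448 and 40854554 reads per double tumour, 36182031 and 41214398 per triple superficial tumour, 35618473 and 40739217 per pigmented tumour and 25982441 and 81076537 per amelanotic tumour were assigned to genes. Assigned reads ranged from 31372 to 7029356 in the primary sorted pools. Regressed pools 37, 68, 69 and 40 held 15875422, 211782, 202306 and 22810799 assigned reads. Estimated transcript counts ranged from 233439 to 1236644 in control, 111815 to 1541760 in primary and 140930 to 626900 in regressed plate pools. They ranged from 109077 to 1238779 in primary cells and from 69292 to 1308975 in regressed cells.

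Genotype at 1 pattern of growth was addressed by comparing triple superficial tumours, which carry the BRAF transgene, with double superficial tumours. Any other difference between the double and the triple fish, such as family or background, cannot be told apart from the transgene. Reads of the human transgene averaged 32.3 ± 32.4 CPM (SD) in the 4 triple superficial tumours, of which tumour 3 had 27 reads (0.746 CPM over all reads), and amounted to 1 read over the 5 double tumours (adjusted p = 0.000245, edgeR). The zinc finger gene znf1179 was higher in triple tumours, at 119.8 ± 47.5 against 3.27 ± 0.919 CPM, a log2 fold change of 5.19 ± 0.39 (SE, adjusted p = 3.07e-06, 4 of 4 tumours). The class II histocompatibility gene mhc2dgb was lower, at 0.0438 ± 0.0271 against 183 ± 166 CPM (log2 fold change -11.97 ± 1.57, adjusted p = 0.00352). The related mhc2dga had 3 reads in the triple and 13382 in the double tumours (adjusted p = 0.0129). These belong to families of similar genes, so their counts are uncertain where reads could be shared. The amino acid transporter gene SLC38A11 rose by 5.92 ± 0.97 on the log2 scale (adjusted p = 0.0258). The gene otoa rose by 6.51 ± 1.38 (adjusted p = 0.0450, 3 of 4 tumours), and nlrc11 fell by 8.65 ± 1.66 (adjusted p = 0.0299). The melanocyte genes MITF (ENSDARG00000003732, 0.57 ± 0.62, adjusted p = 0.787), SOX10 (0.74 ± 0.58, adjusted p = 0.675) and DCT (1.68 ± 0.98, adjusted p = 0.527) did not pass the test. Neither did the proliferation marker mki67 (0.56 ± 0.55, adjusted p = 0.755).

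In this comparison of genotypes, 147 of 22477 genes passed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 119 higher and 28 lower in triple tumours. Of the 23 gene lists, 7 passed camera with a preset correlation. Melanin and melanosome genes (22 members, adjusted p = 0.00177), interferon response genes (15 members, 0.00934) and cell cycle genes (30 members, 0.0103) ranked higher in triple tumours. Endothelial genes (14 members, adjusted p = 0.000261), immediate early genes (23 members, 0.000261), cytosolic ribosomal proteins (83 members, 0.00313) and matrix genes (30 members, 0.0352) ranked lower. Over all genes 0 members of these lists passed by edgeR, where 7 melanin genes were higher and 5 endothelial and 5 immediate early genes lower at an unadjusted p under 0.05. So were 3 interferon genes, 1 cell cycle gene and 1 ribosomal gene on the higher side, and 6 matrix genes lower and 1 higher. DESeq2 called 4 melanin genes higher and 2 endothelial, 2 immediate early and 1 matrix gene lower, and limma-voom 2 melanin genes higher and 1 immediate early and 1 matrix gene lower. Adjusted over the list alone, 4 melanin genes were higher, 3 endothelial genes lower and 1 immediate early gene lower. Among them trpm1b stood at 223 ± 202 against 35.3 ± 23.9 CPM (adjusted p over all genes 0.0793) and the vascular receptor gene KDR at 16.9 ± 3.77 against 94.9 ± 112 (0.124). With an estimated correlation 0 of the 23 lists passed (adjusted p = 0.844 with an estimated correlation for all 7), and 0 lists passed by fry, with 0 and 1 of the 23 at an unadjusted p under 0.05. The count of genes depended on the tool and on single tumours. DESeq2 called 1042 genes, limma-voom 748, a filter of 1 CPM 59 and a fit of only these 2 groups 69. It was 50, 3, 9 and 6 without double tumour 1, 2, 3 or 5, and 10, 60, 26 and 290 without triple superficial tumour 1, 2, 3 or 4. With all 12 triple tumours against the double tumours 2034 genes passed, 1133 higher and 901 lower.

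**Figure D1:**
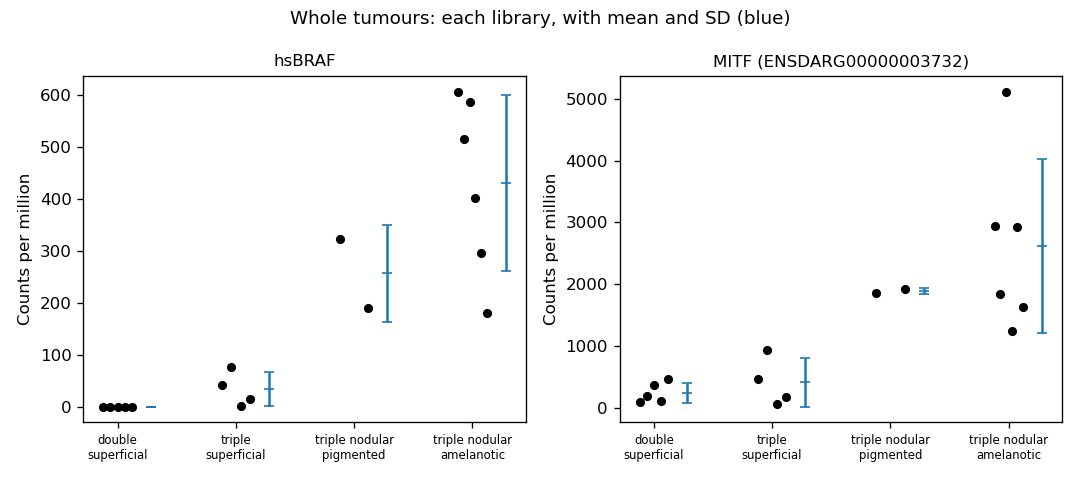
CPM over all reads (linear axis) of the human BRAF transgene and of MITF (ENSDARG00000003732) in each whole-tumour library, by group, with points for tumours and blue bars for the mean ± SD. MITF averaged 249 ± 162 in double superficial, 415 ± 391 in triple superficial, 1890 in pigmented nodular and 2614 ± 1407 in amelanotic nodular tumours, and hsBRAF 33.4 ± 33.1, 256 ± 93.2 and 431 ± 170 in the 3 triple groups.

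Direction of growth within the triple genotype was addressed by comparing 8 nodular with 4 superficial tumours. The melanocyte regulator MITF (ENSDARG00000003732) averaged 2366 ± 1235 against 399.9 ± 386 CPM, a log2 fold change of 2.56 ± 0.66 (adjusted p = 0.00764, 8 of 8 tumours). The neural crest transcription factor gene SOX10 averaged 352 ± 121 against 52.96 ± 49.1 CPM (2.73 ± 0.61, adjusted p = 0.00406). The transgene hsBRAF was higher too, at 377 ± 164 against 32.3 ± 32.4 CPM (3.55 ± 0.80, adjusted p = 0.00429). So was the phosphatase gene DUSP4, which ERK signalling induces, at 221 ± 105 against 14.4 ± 8.11 CPM (3.94 ± 0.63, adjusted p = 0.000917). The keratin gene krt4 was lower in nodular tumours and averaged 448 ± 494 against 3698 ± 1238 CPM (-3.05 ± 0.64, adjusted p = 0.00299). The collagen gene COL1A2 was lower and averaged 98.2 ± 78.0 against 1352 ± 539.7 (-3.78 ± 0.61, adjusted p = 0.000917). DCT (2.28, adjusted p = 0.0797), mki67 (0.97 ± 0.53, 0.150), zebrafish BRAF (-0.38 ± 0.22, 0.173) and the other MITF gene, ENSDARG00000037833 (0.56 ± 0.48, 0.370), did not pass.

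Across all genes, 8581 of 22477 differed between nodular and superficial tumours, 3835 higher and 4746 lower in nodular tumours. The amelanotic tumours alone differed from superficial ones in 10680 genes (4823 higher, 5857 lower) and the 2 pigmented tumours alone, a comparison chosen after seeing the data, in 172 (160 higher, 12 lower). At an unadjusted p under 0.05 by edgeR the counts were 12607 and 4428. The amelanotic tumours have a title series of their own, which holds no superficial or pigmented tumour. Neither growth nor pigment can therefore be told apart from that series in them. In the pigmented tumours alone MITF stood at a log2 fold change of 2.13 (adjusted p = 0.180), SOX10 at 2.39 (0.124), DUSP4 at 2.995 (0.0498), krt4 at -1.60 (0.186) and COL1A2 at -2.71 (0.131).

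Of 22 keratinocyte genes 19 fell in nodular tumours, over all genes and adjusted over the list alone, among them the epidermal regulator TP63 (-2.84 ± 0.60, adjusted p = 0.00307). Of 18 genes of ERK pathway output 13 rose and 2 fell (13 and 3 adjusted over the list alone), among them the ETS factor genes etv5b (2.76 ± 0.41, adjusted p = 0.000709) and ETV4 (3.04 ± 0.55, adjusted p = 0.00151). Melanin and melanosome genes rose in 7 and fell in 1 of 22 cases (5 and 1 adjusted over the list alone), with the melanosome transport gene MLPH at 964 ± 423 against 141 ± 127 CPM. Of 12 iridophore genes 5 rose (5 adjusted over the list alone), such as EDNRB (ENSDARG00000089334, 2.62 ± 0.59, adjusted p = 0.00407). Of 15 interferon response genes 6 rose (6 adjusted over the list alone), such as isg15 (2.26 ± 0.55, adjusted p = 0.00574). Cell cycle genes rose in 5 of 30 cases (0 adjusted over the list alone, 12 at an unadjusted p under 0.05 and 12 by DESeq2), such as the replication helicase gene MCM3 (116.6 ± 38.4 against 50.8 ± 12.25 CPM, adjusted p = 0.0286). Cytosolic ribosomal proteins rose in 12 of 83 cases (0 adjusted over the list alone, 22 at an unadjusted p under 0.05 and 19 by DESeq2) and oxidative phosphorylation genes in 11 of 96 (3). Both list medians were below 0 in the pigmented tumours alone, at -0.34 and -0.05.

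Matrix and mesenchymal genes fell in 16 and rose in 2 of 30 cases (16 and 2 adjusted over the list alone), and the transcription factor gene ZEB1 was among those that rose (2.61 ± 0.39, adjusted p = 0.000667). Of 15 glial genes 10 fell and 2 rose (10 and 2 adjusted over the list alone). Of 18 sterol synthesis genes 12 fell and 1 rose (13 and 1), and the regulator srebf2 was among those that fell (-2.17 ± 0.57, adjusted p = 0.00877, and 0.0530 without superficial tumour 4). Limma-voom called 3 sterol genes lower and 1 higher, with a list median of -1.23 against -2.55, and 15 muscle genes lower. Falls were also counted in 8 of 13 mitochondrially encoded genes (11 adjusted over the list alone), 6 of 8 erythrocyte genes (7) and 5 of 26 skeletal muscle genes (4), such as the globin gene hbaa1 at 245 ± 286 against 2084 ± 1845 CPM. These 14 lists passed camera with a preset correlation, at adjusted p from 3.25e-09 for keratinocyte genes to 0.0229 for iridophore genes. By camera with an estimated correlation 0 lists passed, and 0 of 23 had an unadjusted p under 0.05. The adjusted p = 0.537 with an estimated correlation for the keratinocyte, ERK output and glial lists, 0.656 for the ribosomal list and 0.636 for the other 10. By fry 7 lists passed, 6 of them among the 14.

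Several of these lists lost calls without single tumours or in the 2 pigmented tumours alone. In the pigmented tumours alone 1 ERK output gene and 1 matrix gene passed among the 14 lists, both higher, where an unadjusted p under 0.05 by edgeR was reached by 14 melanin genes higher and 1 lower, 8 and 2 ERK output genes and 4 and 6 matrix genes. It was reached by 1 glial gene higher and 5 lower, 3 and 1 iridophore genes, 3 and 3 oxidative phosphorylation genes and 2 interferon genes higher. On the lower side alone it was reached by 5 keratinocyte, 11 muscle, 4 mitochondrially encoded, 2 erythrocyte and 1 ribosomal genes. The keratinocyte median was then -1.27 against -2.84 in all nodular tumours, the iridophore median 0.15 against 1.30 and the cell cycle median 0.24 against 0.99. Only some of the other medians were as far from 0 or farther in the pigmented tumours alone, at 2.28 against 1.55 for melanin, -4.14 against -2.004 for muscle, -3.70 against -3.03 for erythrocyte, -2.63 against -2.55 for sterol and -0.75 against -0.73 for mitochondrially encoded genes. The sterol genes that fell numbered 1 without superficial tumour 3 and 0 without superficial tumour 4 by edgeR, with 8 and 12 at an unadjusted p under 0.05. The cell cycle genes that rose numbered 1, 3, 0 and 0 without superficial tumour 1, 2, 3 or 4 (11, 14, 6 and 3 at an unadjusted p under 0.05) and 8 without pigmented tumour 1, and limma-voom called 10. The ribosomal genes that rose numbered 2, 1 and 4 without superficial tumour 1, 3 or 4, and 27 without pigmented tumour 1. The oxidative phosphorylation genes that rose numbered 4, 6, 6 and 6 without superficial tumour 1, 2, 3 or 4, and 28 without pigmented tumour 1, and limma-voom called 20 higher. Mitochondrially encoded genes that fell numbered 1 and 2 without superficial tumour 2 or 4, and erythrocyte genes 1 without superficial tumour 4. Muscle genes that fell numbered 2 and 2 without superficial tumour 1 or 2, and iridophore genes that rose 3 without superficial tumour 3.

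The other 9 lists did not pass camera in this comparison of growth directions. Their called members were 3 lower of 14 endothelial genes (list adjusted p = 0.0553), 2 higher and 7 lower of 23 immediate early genes (0.0985), 7 higher and 3 lower of 26 hypoxia and glycolysis genes (0.221), and 10 higher and 8 lower of 21 neural crest genes (0.268). They were 3 higher and 4 lower of 14 genes of the neural crest stem-like state (0.386), 3 lower of 15 T and NK cell genes (0.538), 3 higher and 2 lower of 17 p53 targets (0.724), 4 higher and 3 lower of 20 macrophage and granulocyte genes (0.889), and 2 lower of 10 xanthophore genes (0.889).

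Within the nodular tumours, 6 amelanotic were compared with 2 pigmented ones. The basal keratin gene krt5 was lower in amelanotic tumours and averaged 624 ± 476 against 8890.4 ± 355 CPM (log2 fold change -3.83 ± 0.60, adjusted p = 0.00195, 6 of 6 tumours). The epithelial adhesion gene epcam averaged 107 ± 73.3 against 918 ± 194 (-3.10 ± 0.54, adjusted p = 0.00302). The homeobox gene ALX4 (ENSDARG00000088332) was higher, at 290.1 ± 195 against 13.5 ± 2.83 CPM (4.43 ± 0.83, adjusted p = 0.00437). Also higher were the receptor gene fgfr4 at 548 ± 266 against 62.9 ± 51.8 (3.12 ± 0.82, adjusted p = 0.0247) and the cyclin gene CCND1 (1.88 ± 0.41, adjusted p = 0.00999). MITF (ENSDARG00000003732, 0.56 ± 0.79, adjusted p = 0.705), SOX10 (0.45 ± 0.73, 0.742), the melanin synthesis gene DCT (0.28 ± 1.23, 0.915) and mki67 (1.05 ± 0.68, 0.355) did not pass. Zebrafish BRAF fell by 0.75 ± 0.22 (adjusted p = 0.0391).

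In the comparison by pigment 2163 of 23767 genes passed, 487 higher and 1676 lower in amelanotic tumours, and 10 lists passed camera with a preset correlation. The melanin and melanosome list was not among them (camera adjusted p = 0.0934), with 1 of 22 members lower, 0 higher and a list median of -0.63. Of 22 keratinocyte genes 17 fell (18 adjusted over the list alone; list adjusted p = 2.19e-20, and adjusted p = 0.0937 with an estimated correlation). Of 83 cytosolic ribosomal proteins 12 rose (39 adjusted over the list alone; 8.42e-19), such as RPL35A at 2459 ± 481 against 843 ± 435 CPM. Of 97 oxidative phosphorylation genes 8 rose (4 adjusted over the list alone; 5.22e-09). Of 10 xanthophore genes 4 fell (5 adjusted over the list alone; 0.00671, and adjusted p = 0.453 with an estimated correlation), such as the pteridine synthesis gene gch2 at 132 ± 70.5 against 668 ± 242 CPM. Falls were also counted in 7 of 30 matrix genes (9 adjusted over the list alone; 0.00641), 3 of 23 immediate early genes (5; 0.0221) and 2 of 15 T and NK cell genes (5; 0.0167), such as il2rb (-2.72 ± 0.45, adjusted p = 0.00241). Of 18 ERK output genes 1 rose (0.0117). Cell cycle genes (0.000137) and skeletal muscle genes (0.0449) ranked higher with 0 members called by edgeR over all genes, where 2 and 1 were higher at an unadjusted p under 0.05, DESeq2 called 0 and 3, and limma-voom 0 and 0. With an estimated correlation 0 of 23 lists passed, with 2 at an unadjusted p under 0.05 (adjusted p = 0.814 with an estimated correlation for the other 8), and fry passed the keratinocyte and xanthophore lists. The count of genes was 805 without pigmented tumour 1 and 511 without pigmented tumour 2, where the remaining tumour is assumed to vary like the other groups. It was 660 in a fit of only these 2 groups and 3846 by DESeq2 (1812 higher, 2034 lower). Without pigmented tumour 1 or 2, the keratinocyte genes that fell numbered 14 and 6, the matrix genes 1 and 1, the xanthophore genes 0 and 1, the immediate early genes 0 and 1 and the T and NK cell genes 2 and 0. The ribosomal genes that rose numbered 0 and 9, the oxidative phosphorylation genes 0 and 9 and the ERK output genes 1 and 0. Where 0 passed by edgeR, an unadjusted p under 0.05 was reached by 2 xanthophore, 3 immediate early, 4 ribosomal and 4 oxidative phosphorylation genes without pigmented tumour 1, and by 3 T and NK cell and 2 ERK output genes without pigmented tumour 2.

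Cells at the site of regressed melanoma were compared with primary melanoma cells in 4 regressed and 14 primary sorted pools. Of 29 cell cycle genes 21 fell in regressed pools, and the list was lost with an estimated correlation (adjusted p = 0.0949 with an estimated correlation). The mitotic kinase gene CDK1 had 0 reads in the regressed pools against 183 ± 115 CPM in the primary pools, and was at least 2590.3-fold lower over all reads with 3 counts over the group as the floor (adjusted p = 0.000476, 4 of 4 pools). The proliferation marker mki67 (adjusted p = 0.00555) and the topoisomerase gene TOP2A (adjusted p = 0.00409) were likewise at 0, at least 838-fold and 1013-fold lower. Of 19 melanin genes 6 fell, a list that was lost in the same way (0.0949) and had 6 members higher and 6 lower with upper-quartile scaling. TYRP1 (ENSDARG00000029204), which encodes a melanosomal enzyme, averaged 1.67 ± 2.03 against 176 ± 221 CPM (log2 fold change -6.87 ± 1.81, adjusted p = 0.0129). TSPAN10 averaged 0.2998 ± 0.503 against 67.0 ± 41.6 (-7.03 ± 1.91, adjusted p = 0.0149). MITF (ENSDARG00000003732) averaged 2112 ± 698 against 706 ± 468 CPM and did not pass (1.58 ± 0.68, adjusted p = 0.116), nor did SOX10 (-0.05 ± 0.84, 0.980) and DCT (-4.98 ± 1.83, 0.0824).

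The number of genes with a count, the share of reads outside any feature and a structure of the libraries moved with these groups. Reads outside any feature had a median share of 34.7% in regressed and 13.3% in primary pools, of these and the assigned reads together. Regressed pools 37, 68, 69 and 40 had 7857, 11821, 6090 and 3877 genes with a count, a median of 6973.5 against 11855.5 in primary pools (7692 to 18904), although pool 40 had the most reads. In 4 sorted pools over 10% of assigned reads lay in MALAT1, a nuclear noncoding RNA: 11.99% and 12.6% in primary pools 45 and 46, and 27.8% and 15.4% in regressed pools 37 and 40, against at most 1.46% in the other 14. These 4 libraries against the rest differed in 4765 genes (1283 higher, 3482 lower), and regressed pools 37 and 40 held 98.9% of the reads of the regressed group. Without the 4 libraries, a choice made after seeing the data, the floor allowed only at least 32.95-fold lower for CDK1, 11.2-fold for mki67 and 12.31-fold for TOP2A. Over all reads hsBRAF stood at 0.0630, 18.9, 9.89 and 224 CPM in regressed pools 37, 68, 69 and 40, against 26.3 to 191 in primary pools. Whether the regressed pools held the same kind of cell as the primary pools was not tested.

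Between regressed and primary sorted pools 986 of 12421 genes passed, 523 higher and 463 lower, and the median log2 fold change of all genes was -0.76, so that changes are relative to that shift. With upper-quartile scaling the median was -0.17 and 2829 genes passed, 2327 higher and 502 lower, and with RLE scaling 641 passed (278 higher, 363 lower). DESeq2 called 2120 (363 higher, 1757 lower) and limma-voom 104 (87 higher, 17 lower). The count was 631, 2687 and 198 without regressed pool 37, 68 or 40, 266 with regressed pools of 50 cells only and 3562 with libraries of at least 500000 reads. With a term for the MALAT1-rich libraries 158 genes passed (21 higher, 137 lower), 153 of them among the 986. Without these libraries 365 passed (121 higher, 244 lower), 157 of them shared, and within the MALAT1-rich libraries 6 passed. MITF (ENSDARG00000003732) passed by DESeq2, by limma-voom and with upper-quartile scaling.

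The 21 cell cycle genes that fell in regressed pools (24 adjusted over the list alone; list adjusted p = 3.86e-14, and adjusted p = 0.0949 with an estimated correlation) numbered 15 of 29 without the MALAT1-rich libraries and 12 with a term for them. The list median with genes at 0 set to their floor was -9.23, and -3.29 without the MALAT1-rich libraries. With upper-quartile scaling 20 fell and 1 rose, and limma-voom called 2. CDK1 (adjusted p = 0.0190 with the term and 0.000568 without the libraries) and mki67 (0.0338 and 0.0309) passed both ways. Of the melanin genes 8 were lower and 1 higher adjusted over the list alone (list adjusted p = 0.000450, and adjusted p = 0.0949 with an estimated correlation). Without the MALAT1-rich libraries 6 of 20 fell and with a term for them 2. TYRP1 was lost with the term (-3.47, adjusted p = 0.385) and without the libraries (-6.87, 0.0937), while TSPAN10 passed both ways (0.0268 and 0.0172). The melanin list median at the floor was -3.97, and -2.89 without the MALAT1-rich libraries.

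Of 23 matrix and mesenchymal genes 8 rose in regressed pools (13 adjusted over the list alone; list adjusted p = 2.84e-12), and this list alone passed with an estimated correlation (adjusted p = 0.0203 with an estimated correlation). ZEB1 averaged 1191 ± 2092 against 53.5 ± 31.1 CPM (4.46 ± 0.82, adjusted p = 0.000455, 3 of 4 pools). The intermediate filament gene VIM (ENSDARG00000010008) averaged 188 ± 334 against 2.19 ± 3.37 (6.25 ± 1.25, adjusted p = 0.00103). With a term for the MALAT1-rich libraries 1 matrix gene passed, and without these libraries 0 of 28 by edgeR, where their median was 2.72. ZEB1 was then at 2.71 (adjusted p = 0.229) and 0.70 (0.625). Of 9 xanthophore genes 2 rose (3 adjusted over the list alone; list adjusted p = 7.18e-05, and adjusted p = 0.0723 with an estimated correlation), gch2 at 5080 ± 4317 against 882 ± 1283 CPM (2.52 ± 0.76, adjusted p = 0.0318) and PAX7 (ENSDARG00000070818; 5.29 ± 1.40, 0.0175), and 1 passed with the term and 1 without the libraries.

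Cytosolic ribosomal proteins rose in 4 of 81 cases in regressed pools (4 adjusted over the list alone; list adjusted p = 8.72e-12, and adjusted p = 0.302 with an estimated correlation) and in 78 with upper-quartile scaling. Of 93 oxidative phosphorylation genes 7 fell (5 adjusted over the list alone; 0.000549, and adjusted p = 0.554 with an estimated correlation), with 20 higher and 7 lower under upper-quartile scaling. Iridophore genes rose in 2 of 11 cases (3; 0.000390, and adjusted p = 0.0966 with an estimated correlation), macrophage and granulocyte genes in 1 of 17 (0.0141, and 0.386) and immediate early genes in 2 of 21 (4 higher and 4 lower adjusted over the list alone; 0.0243, and 0.333). Neural crest genes rose in 2 of 15 cases, TFAP2A and PAX7, and camera ranked them higher (0.0213, and 0.0813 with an estimated correlation) although their median was -0.05, or 4.03 with upper-quartile scaling. TFAP2A, which was higher in 2 of 4 regressed pools (2.60 ± 0.69, adjusted p = 0.0130), was at -0.88 without the MALAT1-rich libraries. Keratinocyte genes (7 members, 0.000390, and 0.0723 with an estimated correlation) and mitochondrially encoded genes (13 members, 0.000499, and 0.302) ranked higher with 0 members called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. By fry 4 lists passed, 3 of them among the 12 that passed camera. These 3 were the melanin (fry adjusted p = 0.000241), cell cycle (0.00125) and matrix lists (0.0178), and the other was hypoxia and glycolysis (0.0193).

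The sums per library are given for 4 lists chosen after the list results were seen, so no test of them is reported, and they are CPM over all reads unless given as TMM-scaled. Cell cycle genes summed to 53.7 ± 55.7 CPM in 4 regressed against 2063 ± 1125 in 14 primary pools, or 48.6 ± 39.6 against 1791 ± 1001 TMM-scaled. They stood at 6.25 against 320.4 CPM within the MALAT1-rich libraries and at 101 against 2354 in the rest. Melanin genes summed to 3820.2 ± 1262 against 14706 ± 8993 CPM, at 2932 against 7293 within the MALAT1-rich libraries and 4708 against 15942 in the rest. TMM-scaled, the melanin sums were 6109.6 ± 3279 against 13620.1 ± 7660.4 CPM and the groups overlapped, with 10469 in the highest regressed and 3554 in the lowest primary pool. Matrix genes summed to 4738 ± 1856 against 1491 ± 648 CPM, at 4017 against 1712 and 5458 against 1455. Xanthophore genes summed to 5576 ± 6808 against 1043 ± 820.3 CPM, but to 1753 against 1814 within the MALAT1-rich libraries, and regressed pool 69 alone reached 15714.

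**Figure D2:**
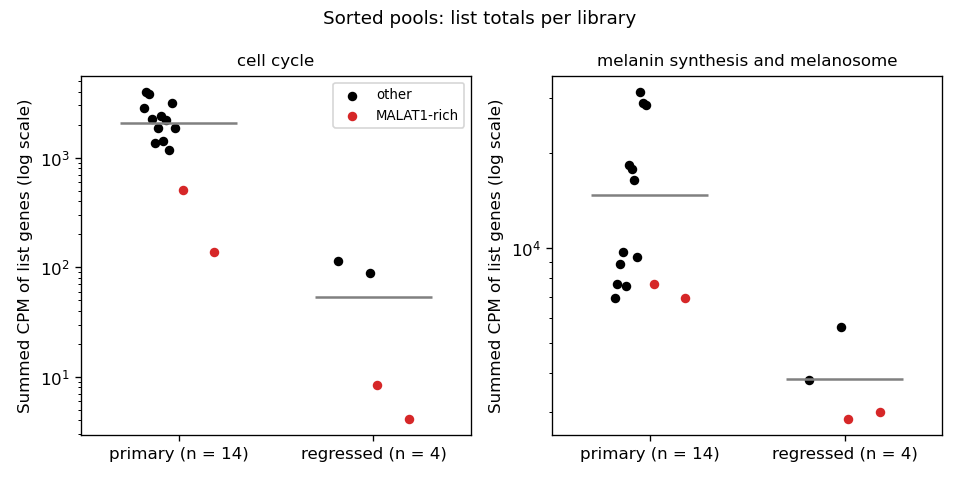
Summed CPM over all reads (log axis) of the cell cycle and of the melanin and melanosome genes in each sorted pool, 14 primary and 4 regressed, with MALAT1-rich libraries in red and a gray line at each group mean. The highest regressed pool had 113 CPM of cell cycle genes against 138 in the lowest primary pool, and 5605 against 6917 CPM of melanin genes. TMM-scaled, these were 99.2 against 269 and 10469 against 3554 CPM, so that the melanin sums of the groups then overlapped.

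The plate pools were quantified per transcript, and the files and the reference tables used here do not pair these transcripts with genes. Between 6 primary and 10 control pools, with the sequencing run as a term, 285 of 13472 transcripts passed, 132 higher and 153 lower in melanoma cells. ENSDART00000145138 had 0 reads in the controls and 277 ± 330 CPM in primary pools, at least 747-fold higher over all reads (adjusted p = 7.31e-09, 5 of 6 pools), and ENSDART00000141177 was at least 374-fold higher (adjusted p = 5.65e-06). ENSDART00000081432 was at 510 ± 222 CPM in controls and 0 in primary pools, at least 543-fold lower (adjusted p = 1.03e-11), and ENSDART00000029308 at least 394-fold lower (adjusted p = 2.38e-10). The median of all transcripts was -1.15, and with upper-quartile scaling it was -0.31 and 1170 transcripts passed (977 higher, 193 lower). It was 0.10 within run GC056829 and -4.95 within run GC056865, where the primary pools were pools 5 and 6, with 5842 and 5250 transcripts with a count against 9767 to 13737 in the other primary pools. Within run GC056829, with 4 primary and 2 control pools, 49 passed (20 higher, 29 lower) and 3 of these 4 transcripts were lost, and within run GC056865, with 2 and 8, 1281 passed (97 higher, 1184 lower). The count was 669 without the run term, 1633 by DESeq2 (222 higher, 1411 lower) and 538 without a filter.

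Between 2 regressed and 6 primary plate pools 145 transcripts passed, 125 higher and 20 lower in regressed pools. ENSDART00000029308 was at 759 ± 738 CPM in regressed and 0 in primary pools, at least 533-fold higher (adjusted p = 9.48e-11, 2 of 2 pools), and ENSDART00000011480 at 0 against 269 ± 168, at least 74.99-fold lower (adjusted p = 0.00382). The count was 467 without regressed plate pool 1, 39 without regressed plate pool 2 and 74 without primary plate pools 5 and 6, a choice made after seeing the data. It was 3 in a fit of only these 2 groups, 628 by DESeq2 (336 higher, 292 lower), 89 by limma-voom, 227 with RLE scaling, 246 without a filter, 275 with a filter of 1 CPM and 359 without the run term. Between 2 regressed and 10 control plate pools 156 transcripts passed, 137 higher and 19 lower. ENSDART00000081432 was at 0 in regressed pools, at least 126-fold lower (adjusted p = 0.000125), and ENSDART00000161027 had 243 reads in regressed and 1 in control pools (adjusted p = 5.36e-05). ENSDART00000999999, 1 of 3 identifiers of placeholder form whose sequence was not analysed here, was at 0 in regressed pools and 713 ± 354 CPM in controls, at least 159-fold lower (adjusted p = 0.0103). This count was 649 and 4 without regressed plate pool 1 or 2, 481 by DESeq2 (353 of them lower), 82 by limma-voom, 255 without a filter, 324 with a filter of 1 CPM and 577 with upper-quartile scaling. The medians of all transcripts were -0.46 and -1.74 in these comparisons, -0.67 and -0.83 with upper-quartile scaling and -0.33 and -1.50 with RLE scaling.

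The labels name no fish for the 87 single cells, so each group is 1 sample and no test was made. The median cell had 2221 transcripts with at least 5 reads among 56 primary and 1701 among 31 regressed cells, and 1962 and 1458 after thinning to 200000 reads, which left out 1 cell of each group. Spike-in entries took a median of 1.87% of the counts in primary and 3.50% in regressed cells, a difference that thinning does not remove. ENSDART00000127667 had at least 5 reads in 22 of 31 regressed cells (70.97%, exact 95% interval 51.96 to 85.8%) and in 6 of 56 primary cells (10.7%, 4.03 to 21.9%). ENSDART00000137866 had them in 19 of 31 regressed (61.3%, 42.2 to 78.2%) and 3 of 56 primary cells (5.36%, 1.12 to 14.9%). In the other direction ENSDART00000078594 had them in 44 of 56 primary (78.6%, 65.6 to 88.4%) and 1 of 31 regressed cells (3.23%, 0.0816 to 16.7%), and ENSDART00000061007 in 47 of 56 (83.9%, 71.7 to 92.4%) and 4 of 31 (12.9%, 3.63 to 29.8%). After thinning, the shares of these 4 transcripts in regressed against primary cells were 70.0 and 9.09%, 60.0 and 5.45%, 3.33 and 76.4%, and 10.0 and 81.8%. By the rule of size, 1736 transcripts were higher in regressed and 1162 in primary cells. A single cell weighs more in a mean of 31 than of 56 cells, so these counts cannot be compared between the groups. Regressed cell 29 had 10440 transcripts with a count, against at most 5299 in the other regressed cells. Without it, a choice made after seeing the data, these counts were 1746 and 1186, and the median regressed cell had 1674.5 transcripts with at least 5 reads. All primary cells were in run GC056829, as were 28 of the 31 regressed cells, with the other 3 in run GC056865.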

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

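The tests of tissue loss, of separate handling and of the number of cells, in both scalings, were chosen only after the result was seen, as were the comparisons of the pigmented tumours alone and of the MALAT1-rich libraries. Of 58 sides tested for a library far from the rest of its group 6 stood out, and chance alone marks about 1 in 20 groups.

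Amelanotic tumour 1 had 25982441 assigned reads, far below the other 5 amelanotic tumours (60553977 to 81076537). Plate control pool 10 had 3.85% of its counts in spike-in entries, against at most 0.293% in the other control pools. The human BRAF transgene had 1 read in double tumour 1, or 0.0245 CPM over all reads like all CPM here unless TMM-scaled, and 0 in the other double tumours. It reached 224 CPM in regressed sorted pool 40, and 18.9, 9.89 and 0.0630 CPM in regressed pools 68, 69 and 37, the last from 1 read. In pool 40 GFP had 3 reads (0.132 CPM), against 235 to 529 CPM in the other regressed pools, although the pools were sorted for GFP from triple fish. GFP stood at 28.3 CPM in double tumour 1 (at most 0.0854 in the other double tumours) and at 51.4 CPM in amelanotic tumour 2 (at most 0.130 in the other amelanotic tumours). No explanation was tested for these values. The placeholder identifier ENSDART00000999999, which was kept among the transcripts of plate pools and single cells, had reads in 26 of 56 primary cells (46.4%) and 4 of 31 regressed cells (12.9%). It had reads in 10 of 10 control, 4 of 6 primary and 0 of 2 regressed plate pools.

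Most genes that passed between nodular and superficial tumours came from the amelanotic tumours, with 10680 genes against 172 for the pigmented ones. At an unadjusted p under 0.05 by edgeR the counts were 12607 and 4428, so the size of this contrast depends on the threshold. The smaller number of pigmented tumours alone is argued against, since the lowest count over the 15 pairs of amelanotic tumours was 5227 and the pigmented pair gave 369 in the same small fits. Depth alone is argued against as well, with 9863 genes for the amelanotic tumours after thinning each library to 25982400 reads. A loss of other tissue that is equal for all cell types is argued against by the keratinocyte genes in all 8 nodular tumours. Their upper quartile of -2.25 lay below the lower quartile of the macrophage and granulocyte genes, -0.84. An unequal loss, or a larger share of tumour cells at the cost of some tissues only, stays open and was not tested. Separate handling of the amelanotic tumours cannot be told apart from pigment or, in these tumours, from growth. They have a title series of their own, which holds no superficial tumour, and 1.57 times the median depth of the superficial ones. No amelanotic tumour is outside that series, and pigment itself stays open and untested.

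Melanin genes ranked lower in regressed sorted pools, with a fitted list median of -2.59. The list passed fry (adjusted p = 0.000241) but was lost by camera with an estimated correlation (adjusted p = 0.0949). With upper-quartile scaling 6 members were higher and 6 lower, with a median of -1.23. Dropout at this level of expression, which the fewer genes with a count in regressed pools would bring to other genes too, is argued against as the whole cause, as the 2.5th percentile of random lists matched on expression was -0.62. The random lists were drawn gene by gene, while the melanin genes vary together (estimated correlation 0.104), so dropout that affects them together stays open. The MALAT1-rich libraries are argued against as the whole cause, since the fitted list median without them was -3.78, or -2.89 with genes at 0 set to their floor. Only 2 regressed pools remain there. The smaller number of cells in regressed pools 69 and 40 cannot be told apart from regression. Regressed pools 37 and 68, of 50 cells like the primary ones, summed to 2857 and 3811 CPM over all reads, below the lowest primary pool at 6917. TMM-scaled, they summed to 6783 and 3335 CPM and pool 37 lay above the lowest primary pool at 3554. The regression of the tumour, the kind of cell in the pools and the fish of origin stay open and untested.

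Cell cycle genes ranked lower in regressed sorted pools, with a fitted list median of -8.98. The list passed fry (adjusted p = 0.00125) but was lost by camera with an estimated correlation (adjusted p = 0.0949). With upper-quartile scaling 20 members were lower and 1 higher. Random lists matched on expression had a 2.5th percentile of -1.61, which argues against dropout shared by all genes at this level as the whole cause. The random lists were drawn gene by gene, while the cell cycle genes vary together (estimated correlation 0.455). The percentile is thus too narrow for such genes, and dropout that affects them together stays open. For single genes at 0 reads the lower number of genes in the regressed libraries stays open. Without the MALAT1-rich libraries the fitted median was -9.08, which is no bound because most members are at 0, and -3.29 with these genes at their floor. That value lies below 0 and argues against these libraries as the whole cause. The smaller number of cells in regressed pools 69 and 40 is argued against as the whole cause, since pools 37 and 68 summed to 8.38 and 113 CPM over all reads, below the lowest primary pool at 138, and to 19.9 and 99.2 CPM TMM-scaled, below the lowest at 269. The regression of the tumour, the kind of cell in the pools and the fish of origin stay open and untested.

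Chance was weighed by drawing 100 splits of the samples into groups of the same sizes. For the genotype comparison 1 split, the real one, gave as many as 147 genes, with 38 as the highest of the others. Without double tumour 2, 3 or 5 the count was 3, 9 and 6, and no splits were drawn for those fits. Chance is excluded for the full set only if the tumours are independent, which the labels do not show. For the growth comparison 1 split gave as many as 8581 genes, with 5614 as the highest of the others, and chance is excluded on the same condition. That highest other split set amelanotic tumours 2, 3, 4 and 6 apart and points to a structure of the samples. For the sorted pools 2 splits gave as many as 986 genes, the real one included. The other, with 1264 genes, set apart primary pools 45 and 46 and regressed pools 37 and 69, of which 3 are MALAT1-rich. With a term for the MALAT1-rich libraries 158 genes passed, and no splits were drawn with that term. The splits treat pools as independent, while the labels do not say which came from the same fish, so chance is not excluded for the sorted pools. For primary against control plate pools 1 split, drawn within runs, gave as many as 285 transcripts, with 47 as the highest of the others. Chance is excluded there only if the plate pools are independent, which the labels do not show.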

How the results depend on the processing

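The alternatives with pigmented tumours alone, with the MALAT1-rich libraries, without primary plate pools 5 and 6, and without regressed cell 29 were chosen only after the result was seen. Named genes kept their side of the threshold, and their direction where they passed, in 555 of 636 alternatives in the genotype comparison. The counts were 818 of 933 by growth, 343 of 455 by pigment, 561 of 738 in sorted pools and 38 of 41, 34 of 47 and 34 of 41 in plate pools. A gene that passed in neither fit was counted as kept even where its sign changed. Named genes lost the threshold without a change of sign in 51, 105, 101, 135, 3, 12 and 6. The shares of the 4 single-cell transcripts kept their direction in 20 of 20. These were picked for the largest differences in the same cells, so this is no separate check.

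For the genotype comparison (147 genes) DESeq2 gave 1042, limma-voom 748, a filter of 1 CPM 59, only the 2 groups 69, all 12 triple tumours 2034 and a block by the number in the title 28. Leaving out single tumours gave 3 to 290. For growth (8581 genes) the pigmented tumours alone gave 172, a block 5831, and leaving out single superficial or pigmented tumours 6031 to 9345. In the pigmented tumours alone ALX4 (ENSDARG00000088332) turned to -0.67 and aste1a to -1.68. For pigment (2163 genes) DESeq2 gave 3846, only the 2 groups 660, leaving out single pigmented tumours 511 to 805, and the block 0 over 4 libraries by edgeR, with 2359 at an unadjusted p under 0.05. Leaving out single tumours gave -7.85 to 0.42 for adcyap1b, -7.33 to 0.39 for pla2g4cl1 and -7.90 to 3.37 for pvalb5, each reversed without pigmented tumour 2. Residual correlations of tumours with the same number ranged from -0.46 to 0.44 by genotype, -0.03 to 0.18 by growth and -0.08 to -0.05 by pigment. The same number was the best match for 1 of 4, 1 of 4 and 0 of 2, too few to take the numbers as pairs.

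For the sorted pools (986 genes) DESeq2 gave 2120, limma-voom 104, RLE 641, upper-quartile scaling 2829, regressed pools of 50 cells 266, libraries of at least 500000 reads 3562, a MALAT1-rich term 158, these libraries only 6, the rest 365, and leaving out single regressed pools 198 to 2687. Leaving out single regressed pools gave -0.18 to 8.51 for ANKRD33B (ENSDARG00000058357), -0.22 to 8.45 for UBAC1 and -0.17 to 5.82 for ltk, each lowest and reversed without regressed pool 40. With pools of 50 cells UBAC1 turned to -1.32 and ltk to -0.74, and with at least 500000 reads EGR3 to -4.73, MMP9 to -5.99 and csf1ra to -9.37. PAX7 (ENSDARG00000070818) was at -0.84 within the MALAT1-rich libraries, and TFAP2A at -0.88 and ltk at -0.15 without them. TFAP2A was at -0.54 by limma-voom, and SOX10 at 6.65 with upper-quartile scaling.

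For primary against control plate pools (285 transcripts) DESeq2 gave 1633, upper-quartile scaling 1170, no filter 538, no run term 669, run GC056829 only 49 and run GC056865 only 1281. For regressed against primary plate pools (145) DESeq2 gave 628, limma-voom 89, RLE 227, no filter 246, a filter of 1 CPM 275, only the 2 groups 3, no run term 359, without primary pools 5 and 6 74, and leaving out single regressed pools 39 to 467. For regressed against control plate pools (156) DESeq2 gave 481, limma-voom 82, upper-quartile scaling 577, no filter 255, a filter of 1 CPM 324, and leaving out single regressed pools 4 to 649. The fitted value of ENSDART00000153551 was -1.83 without regressed plate pool 2 and 14.76 without pool 1 in the comparison with primary pools. That of ENSDART00000189563 was -0.25 without pool 1 and 14.57 without pool 2 in that with controls. Such fitted values against a group at 0 are no bounds. The lone pool is then assumed to vary like the other groups.

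Lists that passed numbered 7, 14, 10 and 12 in the genotype, growth, pigment and sorted pool comparisons, 0, 0, 0 and 1 with an estimated correlation and 0, 7, 2 and 4 by fry. The median primary cell had 520 more transcripts than the median regressed cell, 641 with at least 1 read, 436 with at least 20 reads, 504 after thinning, 500 within run GC056829 and 546.5 without regressed cell 29. Smaller subsets held fewer samples by construction; for the other changes the cause was not tested. Whether sorted and plate pools give the same direction for a gene, and its alternative at an adjusted p under 0.01, were not run, since transcripts were not summed to genes. At the depths, group sizes and spread of the sorted and plate pools together, simulated 4-fold changes were recovered in 0 and in 9.68, 0 and 0% of cases.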
